A study of Mus musculus with 16 samples.

How the data were processed

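Each file of DNA methylation data held read counts per cell and amplicon, not normalized, made from scTAM-seq on the Mission Bio Tapestri instrument per the labels' protocols and deposited by the authors as 1 table per library. The genome build was mm10 per the submitters' processing notes. The aligner, the cell caller and any filter on cells are not given in the sources used here. The protein files held counts of unique molecular identifiers (UMI) per cell and antibody tag, per the file headers as deposited. The tables name amplicons by panel identifiers and do not pair them with genes or positions, so no coordinates are given.

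An amplicon was called methylated in a cell with at least 1 read, and the share of cells so called was the methylation estimate of a library. Libraries, not cells, were the replicates. Constitutive amplicons had a read in at least 90% of cells of every library, and intermediate amplicons had a mean of 25 to 90% over the bone marrow libraries. Libraries held from 3385 to 10059 cells, and a count of 0 cells allows a share of up to 0.0886% in the smallest and 0.0298% in the largest. Doublets were not called. One alternative left out the 5% of cells with the most amplicons. A filter on cells with 80% of constitutive amplicons kept at least 99.88% of cells and so moved almost nothing.

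Groups and replicate numbers came from the sample titles. Old against young and LARRY replicate against LARRY main were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test on the numbers of cells with and without a read, with an intercept per library, over amplicons with a mean share of 2 to 98%, and Benjamini-Hochberg adjustment at 0.05. Means over intermediate amplicons were compared by exact two-sided permutation tests. The association with surface proteins used cells with at least 100 UMI and the rank of the centred log ratio of each protein. Partial correlations given log10 reads and constitutive detection were computed within each library and tested over libraries as Fisher z values with limma 3.58.1. The share of intermediate amplicons methylated per cell was treated in the same way with Spearman's rho. Shared variation was measured on 1500 cells per library after regression on the same covariates, as the variance of principal components above the largest eigenvalue of 10 shuffled matrices, with Leiden clusters at 15 neighbours and resolution 1. Single tissue libraries were described by amplicons at least 20 percentage points outside the range of the 6 LARRY bone marrow libraries. Thinning drew reads without replacement to 1 number per cell and left out shallower cells. For old against young this left out 29.7% and 32.0% of young and 25.4% and 9.05% of old cells. For the tissue libraries it left out 25.0% of lung myeloid cells and at most 2.34% of any other library.

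The tests, thresholds, marker lists, most alternatives and the rule for named items were fixed before the data were examined. The rule named, per tested comparison, the 2 called amplicons with the largest positive and the 2 with the largest negative difference in log odds (or correlation) whose libraries did not overlap between groups (or had the same sign in every library). For single libraries it named the 2 amplicons farthest above and the 2 farthest below the LARRY bone marrow range. Proteins were named when they were on the fixed lists of cell type markers. ESAM and CD49f are on none of these and were named after their values were seen.

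The edgeR comparisons, the protein association and the measure of shared variation were tested on simulated data. The permutation tests of means and the test of the share per cell were not. With a simulated SD between libraries of 0.15 log odds, for old against young 81% of amplicons changed by a log odds of 0.5 and 100% of those changed by 1 were recovered, and 5 of 379 unchanged amplicons were called, over 574 amplicons. For LARRY replicate against main, 86% and 100% were recovered and 8 of 398 unchanged amplicons were called, over 596 amplicons. That SD is below the spread of the data, 0.326 log odds for old against young and 0.404 for the LARRY libraries. At the spread of the data, 70% of amplicons changed by 1 and 100% of those changed by 2 were recovered for old against young, with 3 of 383 unchanged ones called over 582 amplicons. For the LARRY libraries these were 53.5% and 100%, with 7 of 401 called over 600 amplicons. All of these edgeR simulations gave every amplicon the same SD and independent errors, while the spread of the data differed between amplicons. They thus give no error rate for the calls in the data. For the protein association, effects were simulated for CD48 only and tested without the covariates. Of CD48 pairs simulated at log odds of 0.3 and 0.6 per SD, 96% and 92% were recovered, with 3 of 393 unchanged CD48 pairs called. Calls at other proteins, whose centred values depend on CD48, were not counted. The simulation thus gives no error rate for the pairs of all proteins. For shared variation, 0, 5 and 20 simulated clones gave 0, 4 and 15 components above the shuffled matrices, and 15, 5 and 20 Leiden clusters. Alternatives covered the read call, thinning, the scaling between libraries, DESeq2 1.42.0 and edgeR on summed reads, limma, filters and leaving out libraries. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. The protein file listed for the lung myeloid library was left out because it was identical to that of the lung endothelial library and matched the cells of the latter. Lentiviral barcodes were not used here. One amplicon that the rule names for the transplant library is not reported here.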

Results

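DNA methylation was measured in single mouse cells with scTAM-seq on the Mission Bio Tapestri instrument, which takes up single cells in droplets and amplifies a fixed panel of genomic targets in each. In scTAM-seq a restriction enzyme that spares methylated sites cuts the DNA first, so an amplicon gives reads in a cell where its CpG was methylated. The panel held 663 amplicons, known here by their panel identifiers only, because the files do not pair them with genes or positions. The series held 16 libraries with 95930 cells and from 106730790 to 462153992 reads each. In the LARRY experiments, cells carry lentiviral DNA barcodes that mark the offspring of single stem cells. Bone marrow of 4 mice formed the main LARRY experiment and bone marrow of 2 mice its replicate. Native bone marrow, without such barcodes, gave 1 library of an unperturbed mouse experiment, 2 young and 2 old libraries. A transplantation experiment gave 1 bone marrow library. LARRY experiments also gave 4 libraries of other cells, namely lung myeloid cells, myeloid cells of bone marrow and peripheral blood, mature immune cells of bone marrow and spleen, and lung endothelial cells.

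Libraries held from 3385 cells in main mouse 4 to 10059 cells in old library 1. The median number of reads per cell ran from 14693 in the lung myeloid library to 89971 in main mouse 1. At a share near 50%, the exact 95% binomial interval had a half-width of 1.70 percentage points in the smallest library and 0.982 points in the largest. Reads without molecular identifiers are not independent molecules, so intervals cover counting error only. In every library, 77 constitutive amplicons were read in at least 90% of cells, and 13 amplicons stayed under 5% of cells in all of them. A further set of 404 amplicons lay at a mean of 25 to 90% over the 12 bone marrow libraries and is called intermediate here.

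Old and young bone marrow differed at 17 of 579 amplicons tested, with 6 methylated in more cells and 11 in fewer cells of the old libraries. Among called amplicons without overlap between the groups, the largest rise in log odds was at AMPL371788, read in 7.27% ± 2.71 (SD, n = 2) of young and 22.3% ± 11.01 (SD, n = 2) of old cells. AMPL365990 rose from 9.80% ± 0.452 to 27.4% ± 15.1. The largest falls were at AMPL371479, which fell from 85.3% ± 13.2 to 52.0% ± 7.31, and at AMPL376318, which fell from 57.0% ± 19.4 to 16.9% ± 2.94. The median difference was 16.4 points among called gains and 25.5 points among called losses, against 4.04 points over all amplicons tested. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log odds differences were 1.27 with a standard error of 0.327 (adjusted p = 0.00875) at AMPL371788 and 1.18 with a standard error of 0.329 (adjusted p = 0.0173) at AMPL365990. In the same edgeR test they were -1.92 with a standard error of 0.340 (adjusted p = 5.80e-06) at AMPL371479 and -1.90 with a standard error of 0.330 (adjusted p = 5.80e-06) at AMPL376318. The rises were 1.74 each without old library 1, but lost their calls without young library 1 (0.986 and 1.14), young library 2 (1.57 and 1.21) or old library 2 (0.808 and 0.616). The falls were -2.78 and -2.48 without young library 1 and lost their calls without young library 2 (-1.07 and -1.32).

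In the separate native library, these 4 amplicons were read in 8.28%, 2.84%, 97.7% and 79.7% of cells, in the order named. Young and old libraries did not overlap at 252 of 579 amplicons, or 43.5%, where chance gives 33.3%. The labels number the young and old libraries without naming animals, so the p-values rest on the spread between libraries, which may be technical. That spread was largely pooled over amplicons, so a standard error does not show the spread of its own amplicon. AMPL371732, with SDs of 0.04 points in young and 0.052 in old libraries, had a standard error of 0.320 and was not called. AMPL388656, with SDs of 10.2 and 37.6 points, had 0.353 and was called. The count of calls rested on single libraries: in edgeR it was 4 without young library 1, 78 without old library 1, 7 without old library 2, and 0 without young library 2, where 35 amplicons had an unadjusted p below 0.05. It also rested on the read call and the tool, with 7 calls in edgeR at 2 reads, 0 at 5 and at 10 reads (49 and 40 at unadjusted p below 0.05), 0 on summed reads (48 at unadjusted p below 0.05) and 0 with the median log odds difference set to 0, a scaling chosen after seeing the data (102 at unadjusted p below 0.05), against 18 in limma on the shares and 8 in DESeq2 on summed reads. The balance of directions moved as well. In edgeR, 0 amplicons were higher and 7 lower in old libraries at 2 reads, and 7 were higher and 16 lower with thinned cells. The median log odds difference over tested amplicons was 0.132. It was 0.246 without old library 1 and -0.0391 without old library 2.

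**Figure D1:**
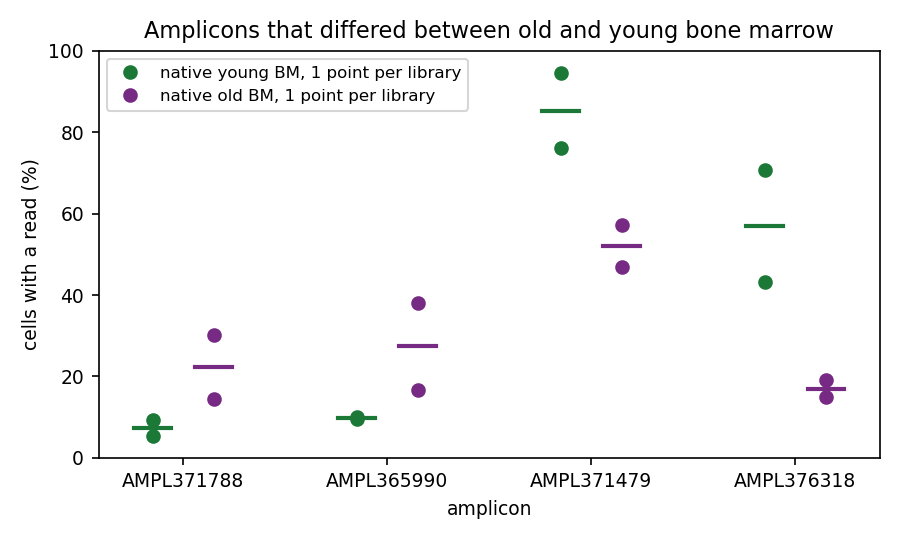
Percent of cells with a read (y axis) in the young and old native bone marrow libraries at the 4 amplicons named for this comparison (x axis). Points are libraries and bars are group means; at AMPL376318 both old libraries lie below both young ones.

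The mean level of methylation did not separate old from young bone marrow. Over intermediate amplicons, 62.8% ± 0.771 (SD, n = 2) of young and 63.6% ± 3.31 (SD, n = 2) of old cell calls were methylated, a difference of 0.879 points. The exact two-sided permutation test gave p = 1, and with 2 against 2 libraries it cannot fall below 0.333. Old library 2 had a median of 50356 reads per cell, against 27421 to 29540 in the other 3. With each cell thinned to 22499 reads the difference was -0.940 points, and without old library 2 it was -1.46 points.

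The replicate LARRY experiment asked whether the bone marrow methylation of the main experiment was found again in other mice. Replicate libraries were methylated in more cells than main libraries at 186 amplicons and in fewer at 3, of 596 tested. Over intermediate amplicons, the mean was 62.5% ± 1.65 (SD, n = 4) in main and 69.4% ± 1.09 (SD, n = 2) in replicate libraries. Among called amplicons without overlap, the largest rises in log odds were at AMPL389970 and AMPL388704 and the largest falls at AMPL371486 and AMPL371251. AMPL389970 was read in 78.5% ± 19.5 of main and 99.6% ± 0.057 of replicate cells. It stood at 95.6% and 95.1% in main mice 1 and 2 and at 63.1% and 60.2% in main mice 3 and 4. AMPL388704 rose from 91.5% ± 3.28 to 99.1% ± 0.502. AMPL371486 fell from 83.8% ± 8.24 to 37.6% ± 21.2 and AMPL371251 from 77.7% ± 4.72 to 63.2% ± 4.25.

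The log odds differences in edgeR's quasi-likelihood test were 3.72 with a standard error of 1.02 at AMPL389970 (adjusted p = 0.0365), 2.38 with 0.377 at AMPL388704 (adjusted p = 0.0113), -2.31 with 0.544 at AMPL371486 (adjusted p = 0.0225) and -0.721 with 0.212 at AMPL371251 (adjusted p = 0.0432). AMPL389970 lost its call without main mouse 3 or 4 or replicate mouse 1 or 2 (3.21, 3.19, 3.82 and 3.63), and AMPL388704 without replicate mouse 2 (1.97). AMPL371486 lost it without main mouse 2 or replicate mouse 2 (-2.41 and -1.64), and AMPL371251 without main mouse 2, 3 or 4 or replicate mouse 1 or 2 (-0.703, -0.794, -0.795, -0.591 and -0.85). AMPL371486 also shrank to -0.992 at a read call of 5 reads and to -0.00742 at 10 reads, where edgeR did not call it (adjusted p = 0.248 and 0.99). The median log odds difference over all tested amplicons was 0.466. Relative to that shift, with the median difference set to 0 after seeing the data (0.0184 was left), 25 amplicons were higher and 33 lower in replicate libraries, so that 43.1% of calls were higher in place of 98.4%. Setting the median log odds of each library equal removed only a part of the shift, leaving a median difference of 0.156, and 44 were higher and 18 lower, or 71.0% higher. In edgeR, AMPL389970 was called in neither setting (adjusted p = 0.0921 and 0.078). The exact two-sided permutation test of the mean over intermediate amplicons gave p = 0.0667, the smallest that 15 arrangements allow. Leaving out 1 library gave 293 calls without main mouse 1, from 99 to 120 without main mouse 2, 3 or 4, 138 without replicate mouse 1 and 4 without replicate mouse 2. Tests on summed reads called 1 amplicon in edgeR and 36 in DESeq2, 24 of them higher, and AMPL371486 turned direction there.

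Across 586 amplicons that were not constitutive, the shares of cells correlated with r from 0.962 to 0.993 between main libraries and from 0.926 to 0.964 between main and replicate libraries. These are correlations across amplicons, which are not independent replicates. Main mice 1 and 2 correlated at 0.989 and main mice 3 and 4 at 0.993, against 0.962 to 0.974 between these pairs. The cause of this pairing was not tested. The edgeR and permutation tests, also those of shared variation below, took the 4 main mice as independent. Their p-values do not allow for such pairs.

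Surface proteins were counted with antibody tags in the same cells of 4 bone marrow libraries, main mice 3 and 4, replicate mouse 1 and the native library, so that methylation could be set against surface phenotype. Of 11267 amplicon and protein pairs, 2120 were associated, at 334 of 593 amplicons. Amplicons were mostly read more often in cells with more Sca-1, a marker of stem and multipotent cells, with 128 positive and 17 negative associations. The same held for ESAM, an adhesion molecule of stem cells and endothelium, with 133 positive and 32 negative, and for CD61, an integrin of megakaryocytes and platelets, with 92 positive and 39 negative. The opposite held for c-Kit, the stem cell factor receptor, with 35 positive and 136 negative, and for CD48, which is low on stem cells, with 40 positive and 112 negative.

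All members of the HSC-like list had associations in both directions. Beside Sca-1 and c-Kit, CD150 had 77 positive and 56 negative, CD27 had 81 and 95, CD34 had 60 and 33, and CD201, the endothelial protein C receptor, had 33 and 40. In the multipotent and lymphoid list, CD135 (Flt3) had 47 positive and 13 negative, and CD127, the interleukin 7 receptor chain, had 72 and 38. In the megakaryocyte list, CD41 had 34 and 30 and CD9 had 25 and 38. Among myeloid, erythroid, mast, dendritic and T cell markers, CD115 had 71 and 38, Ter-119 had 39 and 58, FceRIa had 37 and 51, the class II molecule I-A/I-E had 52 and 34, and CD90 had 33 and 26. CD49f, which is on none of the lists and was named after its values were seen, had 70 and 75. CD16/32 was measured in 2 libraries and was not tested.

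The strongest associations were moderate. AMPL371552 and AMPL371589 followed CD61 with mean partial r of 0.296 ± 0.0188 and 0.292 ± 0.0167 (standard error, 3 libraries), both with limma adjusted p = 0.00109. In limma, AMPL388335 went against CD49f with r of -0.354 ± 0.0149 (adjusted p = 0.000575), and AMPL365938 against CD27, a member of the tumour necrosis factor receptor family, with r of -0.307 ± 0.0147 (adjusted p = 0.000576). Each had the same sign in 3 of 3 libraries. The median over amplicons of the largest absolute r was 0.0665, and 75 amplicons passed 0.2. Without centring of the protein counts, the split was 2994 positive to 387 negative in place of 1159 to 961, and each protein tested had more positive than negative ones, with 132 and 67 for c-Kit, 123 and 35 for Ter-119, 132 and 7 for FceRIa and 28 negative ones for CD48. With no minimum of protein counts per cell, the balance also turned for 10 proteins. More were negative for CD135 (11 positive and 66 negative), CD127 (56 and 87), CD115 (50 and 77), CD150 (43 and 70), CD41 (8 and 30) and CD90 (15 and 27), and more were positive for CD48 (105 and 84), CD27 (132 and 69), CD9 (56 and 46) and CD49f (145 and 52). There c-Kit had 87 and 98 and FceRIa had 27 and 148. With uncentred counts and the total protein count as a covariate, chosen after seeing the data, c-Kit had 58 and 110 and CD48 had 56 and 94. More were then positive for CD201 (103 and 9), Ter-119 (70 and 42), FceRIa (58 and 17), CD27 (96 and 61), CD9 (70 and 30) and CD49f (115 and 78). Leaving out main mouse 3, main mouse 4 or replicate mouse 1 left 2372 testable pairs with 134, 225 and 429 calls.

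**Figure D2:**
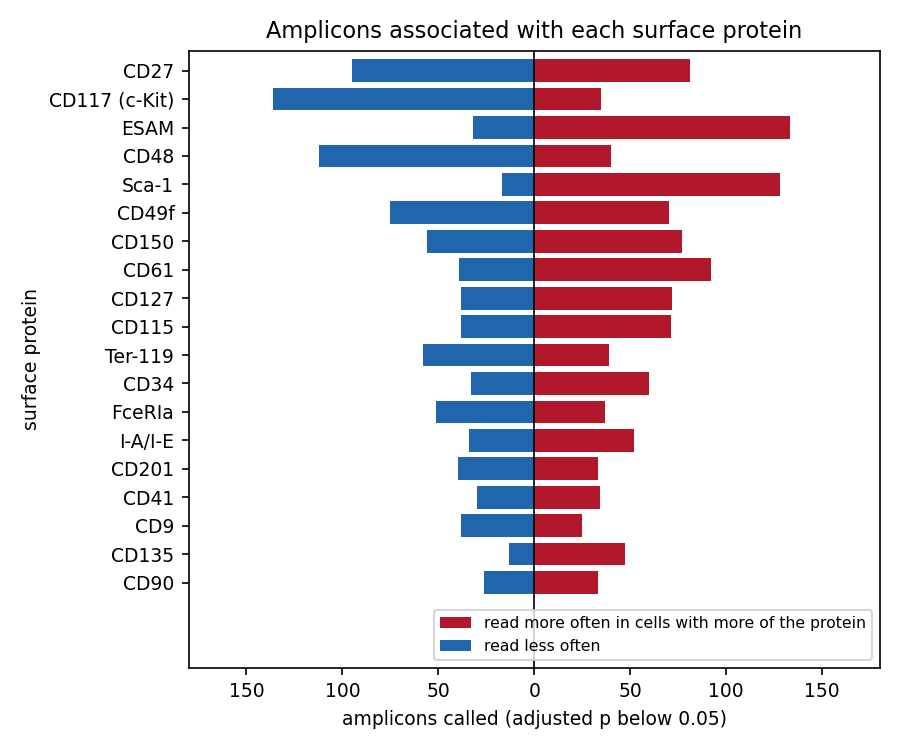
Number of amplicons (x axis) whose read call was associated with each surface protein (y axis) over the bone marrow libraries with protein counts; bars to the right are positive and bars to the left negative associations. Sca-1 and ESAM are mostly on the positive side and c-Kit and CD48 mostly on the negative side.

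The share of intermediate amplicons methylated in a cell rose with Sca-1 and fell with c-Kit in 4 of 4 libraries. The mean partial Spearman rho was 0.137 ± 0.0218 (standard error) for Sca-1 with limma adjusted p = 2.6e-06, and -0.127 ± 0.0218 for c-Kit with adjusted p = 5.92e-06. Here limma pooled the variance over proteins, so every protein had the same standard error, 0.0218 over 4 libraries and 0.0252 over 3. The p-values thus do not rest on the spread of the named protein alone. Single libraries ran from 0.112 to 0.178 for Sca-1 and from -0.185 to -0.0727 for c-Kit. Over 3 libraries, rho was 0.144 for CD61 (adjusted p = 5.92e-06), 0.0835 for ESAM (adjusted p = 0.00707) and 0.063 for I-A/I-E (adjusted p = 0.0387) by limma. Negative rho was also called in limma for CD201 (-0.0902, adjusted p = 0.0041), Ter-119 (-0.0741, adjusted p = 0.0165) and FceRIa (-0.0658, adjusted p = 0.0333), but is not read as an association with these proteins. Their median counts were 0 to 2 UMI per cell, and 36.4 to 48.4% of cells had any for CD201, so that their centred values also depend on the other tags. Sca-1 and ESAM had low counts too, with medians of 1 to 3 and 2 to 3 UMI, so the same limit holds for them. The native library had tags for c-Kit, CD150, CD48 and Sca-1 only, and CD48 made up a mean of 77.5% of UMI there. With uncentred counts and the total protein count of a cell as a covariate, a setting chosen after seeing the data, limma called none of CD201, Ter-119 and FceRIa (rho 0.0477, 0.000542 and 0.0247, adjusted p = 0.0982, 0.982 and 0.407). There it called Sca-1 (0.15), CD61 (0.172), ESAM (0.0983), I-A/I-E (0.0865) and c-Kit (-0.0871) in the same direction as before, and also CD27 (0.0864), CD115 (0.0811), CD127 (0.0889) and CD135 (0.0743). CD48, CD150 and CD27, with rho of -0.0505, -0.0466 and 0.0549, did not pass in limma (adjusted p = 0.054, 0.0662 and 0.0662). In limma, CD48 passed without the native library (rho -0.0772, adjusted p = 0.0105), CD150 at a read call of 5 reads (adjusted p = 0.0133), without covariates (adjusted p = 0.00474) and with no minimum of protein counts, chosen after seeing the data (adjusted p = 0.0217), and CD27 in the latter 2 settings (adjusted p = 0.0105 and 0.0099). Without centring and without that covariate, CD48, CD150 and CD27 passed in limma with positive rho of 0.117, 0.0846 and 0.175 (adjusted p = 0.000246, 0.00201 and 1.1e-05). There, the mean rho of c-Kit, CD201, Ter-119 and FceRIa turned positive, to 0.0374, 0.123, 0.0772 and 0.104. With no minimum of protein counts per cell, limma no longer called Sca-1 (rho 0.0613, adjusted p = 0.106), c-Kit (rho -0.0322, adjusted p = 0.412) or ESAM (rho 0.0396, adjusted p = 0.331). ESAM was not called without covariates either (rho 0.0258, limma adjusted p = 0.489). Without covariates, limma still called Sca-1 (rho 0.0666, adjusted p = 0.0105) and c-Kit (rho -0.0802, adjusted p = 0.00474). There c-Kit no longer had the same sign in all 4 libraries.

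Methylation changes that cells pass to their offspring could mark clones, and the study set such marks against the lentiviral barcodes, which are not used here. For this question, 169 intermediate amplicons that were not called with any surface protein were examined for variation shared between amplicons over 1500 cells per library. In the main draw of cells, libraries of the barcoding and transplantation experiments held more of it than native bone marrow. The variance beyond that of shuffled calls was 8.50%, 8.45%, 5.68% and 7.02% in main mice 1 to 4, and 7.77% and 8.34% in replicate mice 1 and 2. It was 9.81% in the transplant library, 8.98% in bone marrow and spleen immune cells, 5.81% in bone marrow and blood myeloid cells, 5.42% in lung myeloid cells and 4.85% in lung endothelial cells. It was 1.48% in the native library, 1.72% and 1.57% in the young libraries, and 2.52% and 4.00% in the old libraries. Over 10 other draws of cells, the lung endothelial library (4.40 to 4.94%) and old library 2 (3.77 to 4.42%) overlapped. The screen against surface proteins used bone marrow libraries only. It did not remove amplicons that differ between cell types within the mature and endothelial libraries. From 11 to 13 components exceeded the shuffled calls in LARRY bone marrow, 4 in the native library, 6 in each young library, 8 in old library 1 and 10 in old library 2.

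Old libraries held 3.26% ± 1.05 (SD, n = 2) and young libraries 1.65% ± 0.106 (SD, n = 2), a difference of 1.61 with an exact two-sided permutation p = 0.333, the smallest that 2 against 2 allows. The gap between LARRY and native bone marrow rested on the choice of amplicons. Over all intermediate amplicons the lowest LARRY library minus the highest native library was -2.90, against 1.68 over the 169. There, lung endothelial cells (8.50%) and bone marrow and blood myeloid cells (8.88%) also lay below old libraries 1 and 2 (10.1% and 13.0%). Leiden cluster counts are not read as counts of clones: 5 and 20 simulated clones gave 5 and 20 clusters, but simulated cells with 0 clones gave 15.

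**Figure D3:**
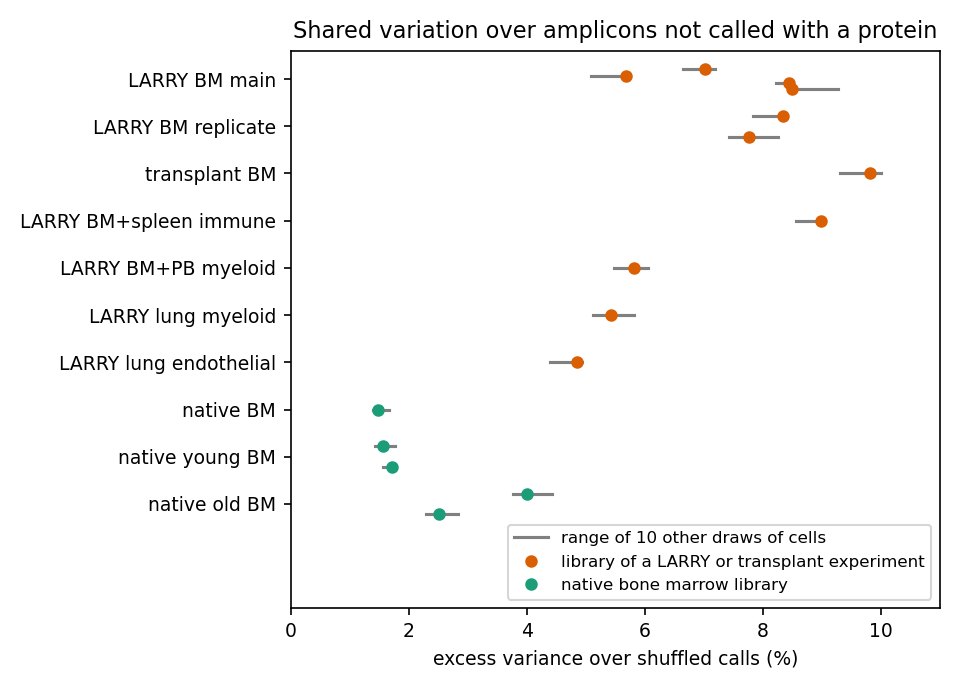
Variance beyond shuffled calls, in percent (x axis), for each library by group (y axis), over amplicons not called with a surface protein. Points are libraries and grey lines the range over 10 other draws of cells; LARRY bone marrow libraries lie from 5.68% up and native bone marrow libraries at 4.00% or below.

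Tissue libraries had no replicates and were not tested. The title of the lung endothelial library names endothelial cells, while its characteristics give immune cells, and the title was followed. It stood apart from all blood libraries, with 223 of 663 amplicons at least 20 percentage points outside the range of the 6 LARRY bone marrow libraries, 111 above and 112 below. AMPL388255 was read in 97.8% of endothelial cells (exact 95% binomial interval 97.4 to 98.2%) against 1.68 to 4.11% in LARRY bone marrow, and AMPL376554 in 96.7% against 4.72 to 9.69%. AMPL376948 was read in 5.39% of endothelial cells (4.85 to 5.97%) against at least 93.4%, and AMPL388272 in 2.37% against 85.9 to 91.4%. Across amplicons, the endothelial library correlated with the other 15 libraries at r from 0.341 to 0.460, and those 15 with each other at r from 0.865 to 0.993.

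Mature blood cells left the LARRY bone marrow range at 22 to 31 amplicons. In bone marrow and spleen immune cells, 20 amplicons lay above and 3 below, with 17 and 17 at a read call of 5 reads and 42 and 1 with thinned cells. AMPL388656 was read in 65.8% of these cells (exact 95% binomial interval 64.7 to 66.9%), in 36.2% of bone marrow and blood myeloid cells, in 26.1% of lung myeloid cells and in 2.21 to 9.58% of LARRY bone marrow cells. AMPL371297 was read in 21.9%, 15.3% and 11.3% of the same mature cells, against 52.7 to 82.5%. At AMPL388656, lung myeloid cells lay 16.6 points above the range, short of the rule of 20 points. High values of AMPL388656 were not particular to mature cells. In native bone marrow it was read in 13.8% and 28.3% of young and 19.7% and 72.8% of old cells. Lung myeloid cells had 1 amplicon above and 21 below, and bone marrow and blood myeloid cells 5 above and 26 below. These libraries were shallower, and the balance turned with depth. With all cells thinned to 11093 reads, a setting chosen after seeing the data, it was 10 above and 1 below in lung myeloid cells and 16 above and 5 below in bone marrow and blood myeloid cells. The thinned shares of AMPL388656 were 61.0%, 29.6% and 23.3% against 0.729 to 3.80%. Those of AMPL371297 were 10.5%, 7.37% and 8.13% against 11.4 to 50.3%.

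The native library had 11 amplicons above and 1 below, with AMPL388687 read in 86.4% of its cells against 16.2 to 37.0%, and AMPL366081 in 13.4% against 33.6 to 58.0%. The transplant library had 5 above and 9 below, with AMPL355580 at 36.2% against 84.6 to 91.8%, and the balance turned to 16 above and 4 below with thinned cells. For background, a LARRY bone marrow library set against the other 5 had from 0 to 7 amplicons outside.

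**Figure D4:**
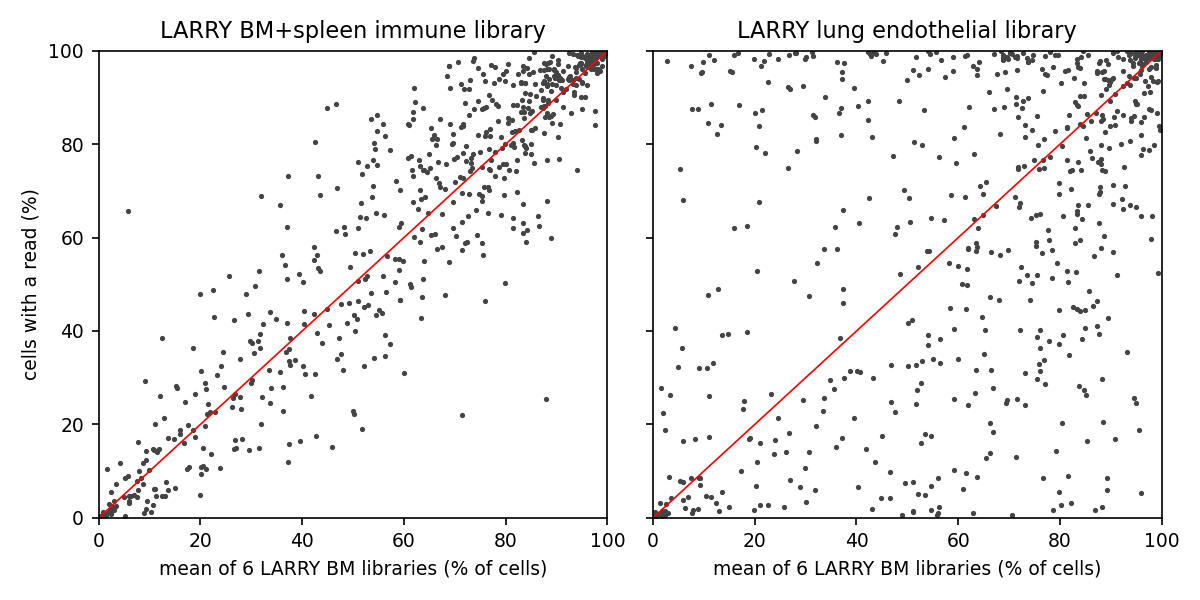
Percent of cells with a read per amplicon in the bone marrow and spleen immune library (left, y axis) and the lung endothelial library (right, y axis) against the mean of the 6 LARRY bone marrow libraries (x axis); the red line marks equal values. Points of the endothelial library leave the line over the whole range, with 223 amplicons at least 20 points outside the LARRY bone marrow range.

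Lymphoid and myeloid cells were not compared, because no protein cluster rested on 3 markers of a class. In the bone marrow and spleen library, 5359 cells had at least 100 protein counts. Clusters led by a single protein held 179 cells with high Siglec-F, an eosinophil and alveolar macrophage protein, 136 with high CD8, and 122 with high Ly-6G, a neutrophil protein. The T cell protein CD3 had a mean z of -0.133 in the CD8 cluster, the second highest of the tags used. The second highest tags of the Siglec-F and Ly-6G clusters were negative as well (-0.187 and -0.374). Centring lowers the other tags where a single tag is high, so the value for CD3 does not decide on T cells. Between each of these 3 clusters and the rest of the library, amplicons that differed by at least 20 points were found for the CD8 cluster alone, 9 higher and 2 lower. At the coarser resolution of 0.5, a CD8 cluster of 101 cells had 32 higher and 9 lower.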

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

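Chosen only after the result was seen were the limits for thinning and for leaving out libraries in old against young, both planned as alternatives, and the tests of LARRY libraries by thinned mean, digestion and detection and of 2 genotypes, while thinning for shared variation was added after the data were examined, with its limit set before its result was seen.

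Old and young bone marrow differed at 17 amplicons. Deeper sequencing of old library 2 does not account for them, since 17 of the 17 were called again with each cell thinned to 1 number of reads. The calls rest on few libraries: without young library 2, 0 of them were called in edgeR (35 amplicons at unadjusted p below 0.05). Whether a shift between stem-like and progenitor cells contributes was not decided. Over 16 called amplicons, the difference followed the association with CD150 with r of 0.627 (permutation p = 0.00961, adjusted over 6 proteins 0.0577). This r was the largest of 6 and misses the limit set for it. Sca-1 and CD201 had r of 0.557 and 0.504, but CD27, c-Kit and CD34 had -0.43, -0.365 and -0.0914. Over all 569 amplicons, r with CD150 was 0.257 to 0.466 for differences between old and young libraries. It was 0.345 between the old libraries and 0.0276 between the young ones. With CD27, r was -0.515 to -0.319 between old and young libraries, -0.199 between the old and -0.13 between the young ones. With CD201 it was 0.139 to 0.473, with 0.306 between the old and 0.23 between the young libraries. With CD34 it was 0.0229 to 0.393, and with Sca-1 and c-Kit it took both signs. The permutation treats amplicons as independent, which they are not. Age itself and differences between single animals also stay open.

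LARRY replicate libraries were methylated in more cells than main libraries at 186 of 189 called amplicons. Deeper sequencing of the replicate does not account for this, since the lower replicate library stayed 4.40 points above the highest main library with thinned cells. Less complete digestion at 1 rate for every amplicon does not account for all of it: 27 amplicons under 20% in every main library, each read in at least 50% of cells of a library outside LARRY bone marrow, rose by a median of 6.96 points (upper quartile 10.4) where 16.5 would have been needed, and a part stays open. Lower detection in the main libraries may contribute: after thinning, 0 of 4 main libraries read constitutive amplicons as often as the lower replicate library, with 98.4%, 97.8%, 97.3% and 97.0% against 98.8% and 98.5%. The test looked at this order only, not at whether gaps of this size could matter. Main mouse 1 and replicate mouse 2, at 98.4% and 98.5%, had thinned means over intermediate amplicons of 60.2% and 66.2%. A biological difference between the mice of the experiments was not tested and stays open.

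LARRY bone marrow libraries held more shared variation than native ones over amplicons not called with a protein, with a mean of 7.63% ± 1.11 (SD, n = 6) against 2.26% ± 1.06 (SD, n = 5) and an exact two-sided permutation p = 0.00216, the smallest its 462 arrangements allow. Reads per cell do not account for it, since with thinned cells the lowest LARRY library stayed 0.96 above the highest native one. The first component held at most 44.7% of the excess in any LARRY bone marrow library. This does not decide on a mixture of 2 genotypes, since other shared variation beside a mixture would also lower that share. The first component held 51.1% in the native library and 56.1% in young library 2. A few large clones in the barcoding experiments were not tested as an explanation and stay open, as do other differences between the experiments, which coincide with the LARRY procedure. Over all intermediate amplicons the lowest LARRY library minus the highest native one was -2.90 (exact permutation p = 0.0606).

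Main mouse 3 stood apart from the other 3 main libraries in its number of cells, 5478. Main mouse 1 stood apart in the mean share over all amplicons, 63.7%. Over 14 measures examined in this way, 0.7 such values are due by chance and 2 were found. The rho between the methylated share of a cell and CD48 was 0.0299 in the native library and negative in the 3 LARRY libraries, a difference that was not tested. Of the lung endothelial cells, 99.6% were found in the protein file listed for the lung myeloid library, against 22.2 to 24.6% of the cells of other libraries. Antibody tags against human proteins only gave 1428 UMI in the bone marrow and blood myeloid library, or 0.0938% of its UMI, where isotype controls gave 6.73%.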

How the results depend on the processing

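Alternatives named here as added were chosen after the data were seen, as was the absence of a UMI minimum for the share per cell. The cause of the changes below was not tested, except where a setting left fewer libraries. Of 184 alternatives of the named amplicons, 105 kept direction and call, 76 kept direction and lost the call and 3 reversed. Of 126 alternatives of the protein correlations, 76 kept direction and call or lack of a call, 4 lost and 16 gained a call and 30 reversed. Shares near 50% carry a counting error of up to 1.70 points, and depth limits what a read call at 5 or 10 reads can show.

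For old against young, with 17 calls, edgeR gave 7 at 2 reads, 0 at 5 reads (49 at unadjusted p below 0.05), 0 at 10 reads (40) and 0 on summed reads with TMM or DESeq2 size factors (48 each), where DESeq2 gave 8 and limma on the shares 18. Leaving out 1 library gave 0 to 78 calls. Added settings in edgeR gave 28 calls with cells thinned and medians set equal (which left a median difference of 0.0848, against 0.00974 with thinning alone), 0 with the median difference set to 0 (102 at unadjusted p below 0.05), 0 with thinning as well (99), and 0 to 27 with thinned cells and 1 library left out. The difference in mean share was -0.940 with thinned cells and from -1.46 to 3.22 with 1 library left out, and kept its direction otherwise.

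For LARRY replicate against main, with 189 calls, edgeR gave 47 at 5 reads, 2 at 10 reads, 62 with medians set equal, and 1 on summed reads with either TMM or DESeq2 size factors, and DESeq2 gave 36. Leaving out 1 library gave 4 to 293 calls. Added settings gave 69 with thinning and medians set equal, 58 with the median difference set to 0 and 70 with thinning as well. AMPL371486 shrank to -0.992 at 5 reads and -0.00742 at 10 reads, lost its call there and reversed on summed reads, to 0.208 in edgeR with TMM, 0.194 with DESeq2 size factors and 0.194 in DESeq2.

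With the replicate number as a replicate block, old against young gave 16 calls and a mean difference of 0.879, and LARRY replicate against main gave 73 calls. Across amplicons, the deviations of same-numbered libraries from their group means correlated at r of 0.0665 for the young and old libraries. For numbers 1 and 2 of the LARRY libraries, r was -0.183 and -0.276. A group of 2 libraries holds only 1 contrast, so these values do not decide whether the numbers pair the libraries.

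Protein counts without centring gave 3381 associations in place of 2120 and 18 proteins called with the share per cell in place of 8. There rho turned to 0.0374 for c-Kit, 0.0846 for CD150, 0.123 for CD201, 0.128 for CD41, 0.117 for CD48, 0.143 for CD49f, 0.144 for CD9, 0.104 for FceRIa and 0.0772 for Ter-119. With uncentred counts given the total UMI, an added setting with 2396 associations and 9 proteins, it turned to 0.00204 for CD150, 0.0477 for CD201, 0.0156 for CD41, 0.01 for CD48, 0.0368 for CD49f, 0.0458 for CD9, 0.0247 for FceRIa and 0.000542 for Ter-119. Without a UMI minimum it turned to 0.128 for CD49f, 0.0789 for CD48, 0.0508 for CD9, -0.0862 for CD135, -0.0641 for CD127, -0.0458 for CD115 and -0.0323 for CD90. Without covariates it turned to -0.00145 for CD127, -0.0127 for CD135, -0.0104 for CD34 and 0.0328 for CD9, and at 5 reads to 0.00503 for CD49f and -0.00156 for CD90. Leaving out 1 library gave 134 to 2244 associations and 2 to 9 proteins, with fewer pairs tested where a LARRY library was left out.

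Over all intermediate amplicons the excess variance of old minus young was 3.53 in place of 1.61, and the lowest LARRY minus the highest native library was -2.90. The median number of Leiden clusters was 7 at resolution 0.5 and 20 at resolution 2. Amplicons outside the LARRY bone marrow range were 50 in lung myeloid cells and 7 in the native library at 5 reads. At 10 points they were 56 in lung myeloid, 102 in bone marrow and blood myeloid, 86 in bone marrow and spleen, 32 in native and 47 in transplant libraries. With thinned cells, an added setting, they were 11 in lung myeloid and 43 in bone marrow and spleen libraries. Alternatives of lymphoid against myeloid cells were not run, since that comparison was not made.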

Other observations

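Every test in this part was chosen after the result was seen.

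Lung endothelial cells read 26 amplicons in over 90% of cells that all 15 other libraries read in under 50%, and 15 amplicons in under 10% of cells that the others read in over 50%. Within the bone marrow and spleen library, a cluster of 848 cells led by B220, a B cell protein, differed from the rest by at least 20 points at 21 amplicons upward and 4 downward. A cluster of 647 cells led by Ly-6C, a monocyte and neutrophil protein, differed at 0 amplicons upward and 12 downward. These clusters were led by 1 protein each, were not named as cell types and depend on the resolution: at 0.5, none was led by B220 or Ly-6C, and clusters of 2585 cells led by NK1.1 and 2205 cells led by CD11b differed at 7 and 1 amplicons upward and at 1 and 13 downward.

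Lung myeloid cells and bone marrow and blood myeloid cells left the LARRY bone marrow range at 14 shared amplicons, all in the same direction, where independent lists give 0.831 and simulated unchanged libraries gave at most 2. With the LARRY libraries split into separate sets, the shared number was 18 against 1.36 and 14 against 1.15 for independent lists. The split does not decide on an effect of the shared range. It parted main mouse 1 from 2 and main mouse 3 from 4, which correlated at r of 0.989 and 0.993. A deviation common to the LARRY libraries would thus enter both sets. The simulation also took amplicons as independent. With thinned cells the shared number was 9 against 0.249, but only 1 of the 14 was shared in the same direction at both depths. The excess is not particular to the myeloid pair. Bone marrow and blood myeloid cells shared 8 amplicons with bone marrow and spleen immune cells against 0.268 for independent lists (13 against 1.02 with thinned cells). Lung myeloid cells shared 7 with the transplant library against 0.293 and 13 with lung endothelial cells against 3.71. Both myeloid libraries were shallower than LARRY bone marrow, so depth stays open as a cause of the 14.

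The separate native library lay nearer to the young than to the old mean at 17 of the 17 amplicons called between old and young. Among amplicons not called it did so at 292 of 562, or 52.0%, and among those not called with no overlap and at least 10 points of difference at 48 of 81, or 59.3%. The same would be seen if the old libraries stood apart for a reason other than age, and the age of this library is not among the labels used here, so the test does not decide on an effect of age.

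AMPL366827, singled out after its values were seen, was read in 98.6%, 100%, 99.4% and 99.9% of cells of main mice 1 to 4, in 100% of cells of replicate mouse 1 and of the native library, and in 30.2% of cells of replicate mouse 2. In the young libraries it was read in 26.7% and 30.4% of cells, and in the old libraries in 40.2% and 22.2%. It was read in 71.5% of transplant cells, 75.7% of lung endothelial cells, 49.4% of lung myeloid cells, 30.4% of bone marrow and blood myeloid cells and 25.4% of bone marrow and spleen cells. The cause was not tested.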
